A study of Mus musculus with 11 samples.

How the data were processed

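Gene expression was measured in livers of 11 male mice, 4 WT, 3 β-catΔEx3 and 4 β-catΔEx3:Myc, each on its own 1-colour (Cy3) Agilent mouse array of the 8x60K format. Per the labels, the strain was largely B6SJL with some 129S6, total RNA was used, and the mice were 22 to 40 days old. An age for each mouse is given only for the 3 arrays of slide 4 (31 days for WT, 29 days for β-catΔEx3:Myc and 30 days for β-catΔEx3), so age could not be entered in the fit. The labels carry no shared animal or litter number, so no samples were paired.

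Per the file headers, the authors read the arrays with Agilent Feature Extraction 10.7.1.1. The authors deposited one file per array with processed signals in scanner intensity units, background-subtracted and not on a log scale. The deposited files also hold median foreground and background intensity and flags for spots that are saturated, well above background or outliers. The authors also deposited a matrix of log2 processed signals that were quantile normalized between arrays. Each of its columns had a median of 4.51, its values ranked the probes exactly as the scanner signals did, and genes were not centred. The scanner files were used for the values here and the matrix for an alternative.

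Of 59305 spots that are not controls, spots flagged as outliers on an array (137 to 209 per array) were left out, and the spots of each of 55681 probes were averaged on the log2 scale. Each array was scaled by subtracting its 75th percentile of log2 processed signal. Probes well above background on at least 3 arrays were kept (29697 probes). The files name probes only by accession, and these were matched to symbols in a RefSeq table of the mouse, which gives names and no coordinates. A symbol was found for 26582 probes (20145 symbols) and none for 29099, which were treated as items of their own. Where a gene had several probes, the probe with the highest mean over the 11 arrays was used. Among the called genes with several kept probes, 224 of 1851, 254 of 2077 and 1 of 13 in the 3 comparisons had probes of both signs. These are signs of the log2 fold change, whatever its size. The choice left 22283 items to test, 13963 with a symbol and 8320 without. The genome positions of the probes are not given here, because no genome build comes with the symbols.

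Groups were compared with limma 3.58.1 in R 4.3.3 (files were read with the package data.table, version 1.17.8). A model of 3 group means was fitted to all 11 arrays with empirical Bayes moderation (residual degrees of freedom 8, prior 2.51), and tests were 2-sided with Benjamini-Hochberg adjustment over all items of a comparison, at a threshold of 0.05. The comparisons were β-catΔEx3 against WT, β-catΔEx3:Myc against WT, and β-catΔEx3:Myc against β-catΔEx3. Slide was fitted as a fixed block for the blocked values. Where a gene was at the background on all arrays of the lower group, a lower bound of the fold was computed and the fitted fold was not printed. The bound sets each array of the lower group to the lowest signal that passed as well above background on that array, or to the gene's own signal if that was higher.

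Gene lists (30, with 637 entries, 624 matched to a symbol) were written before the data were examined. The osteogenic list had 4 measured genes and was not tested. The other 29 lists were those of Wnt feedback targets, perivenous, periportal and mature hepatocyte genes, ribosome biogenesis, cell cycle, fetal liver, biliary, Nrf2, p53, Atf4 and unfolded protein response, acute phase, inflammatory and interferon genes. They further held markers of macrophages, neutrophils, lymphocytes, erythroid cells, stellate cells, endothelium and pancreatic acini. The last were glycolysis, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, bile acid, cytochrome P450, male-biased and female-biased genes. They were tested with camera (preset correlation 0.01), which compares a list with all other genes, and the 87 tests of 29 lists in 3 comparisons were adjusted together. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in one direction, were run beside it. Lists added after the data were seen are given in the closing section.

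The rule for naming genes was set before the data were examined. In each comparison it takes the 10 highest and 10 lowest fold changes among called genes whose groups do not overlap, that are above background on every array of the higher group and that have a symbol. To these it adds up to 3 called genes of each list with the largest change, or the gene with the highest signal if none was called, and Ctnnb1, Myc and Nfe2l2. The text names a subset of these genes, chosen after their values were seen, and some results are withheld and not reported here. Positions of an array on the axis between the mutant groups were computed over 200 genes chosen without that array.

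The alternatives set before the data were examined were quantile normalization, median scaling, no scaling, normexp background correction, other filters, other handling of several probes, array weights, a trended and robust fit, a fit of the 2 compared groups alone, slide as a fixed or random block, slides 2 and 4 alone, the deposited matrix, a fold limit, a threshold of 0.01 and leaving out each array. Normexp was run on the median signal because the files hold no mean signal. The 75th percentile over probes detected on all 11 arrays and scan date as a fixed block were added after the data were seen.

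The arrays were checked for depth and duplicates. The 75th percentile of signal was 227 to 354.3, its median 12.9 to 20.7, and 49.0% to 53.4% of probes were well above background. No array was a copy of another. The analysis was tested on simulated data of the same size and spread, with 200 of 22283 items changed. It recovered 0% of 1.5-fold, 20.9% to 35.8% of 2-fold and 72.7% to 80.3% of 4-fold changes, with 2, 6 and 3 false calls in the 3 comparisons.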

Results

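Gene expression was measured in liver tissue of 11 male mice on 1-colour Agilent mouse arrays. Of these, 4 livers came from wild-type (WT) mice, 3 from mice labelled β-catΔEx3 and 4 from mice labelled β-catΔEx3:Myc. β-catenin carries the Wnt signal to the nucleus, and the form that lacks the stretch encoded by exon 3 escapes the phosphorylation that marks it for degradation. Myc is a transcription factor that drives growth and ribosome production. The series presents the mice as models of hepatoblastoma, a liver tumour of early childhood, and gives the search for therapeutic targets as its purpose. It speaks of livers that bear tumours for all samples, WT included, and does not say whether tumour or the tissue around it was taken. Its design counts the last 4 livers only as expressing c-Myc, and that they carry both changes rests on their labels. The upper quartile (75th percentile) of the processed signal lay between 227 and 354.3 across the arrays, 49.0% to 53.4% of the probes were well above background, and no spot was saturated. Data of the same size and spread were simulated with 200 of 22283 items changed. At most 80.3% of 4-fold changes and 35.8% of 2-fold changes were recovered in any comparison. The real comparisons with WT called far more genes, which makes the adjustment less strict, with smallest called folds of 1.27 and 1.24. The simulated shares therefore do not apply to them.

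The arrays lay on 4 slides. Slide 1 held WT replicates 1 to 3, slide 2 held replicates 1 and 2 of both mutant groups, slide 3 held β-catΔEx3:Myc replicate 3 alone, and slide 4 held 1 array of each group. A fit with slide as a block compares arrays within slides, so its comparisons with WT rest on WT replicate 4. Its values are given as blocked values, except for bounds. Where it ended a call at an adjusted p of 0.05 the blocked adjusted p is given too, or for bounds the loss is stated. Fold changes come from a limma fit to all 11 arrays, given as folds and as log2 fold changes (log2FC) ± their standard error with 4 WT, 3 β-catΔEx3 and 4 β-catΔEx3:Myc arrays. In brackets after a list, the counts adjusted over the list alone follow those adjusted over all genes tested. Every list call was lost when the correlation between its genes was estimated, and that adjusted p is given as estimated. Where leaving out a single array moved a called fold by over 1.5 times, the log2FC without it is given, except for bounds. A fold is given as a bound (at least) where the lower group had no array above background. The bound holds for the background-subtracted signal, and the fold with normexp background correction, whose offset shrinks folds of dim genes, is given beside it.

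The arrays separated first by the presence of mutant β-catenin. The first principal component held 56.2% of the variance and parted all WT from all mutant arrays. The second component held 9.6% and placed the 3 β-catΔEx3 arrays on the other side of 0 from β-catΔEx3:Myc replicates 1, 2 and 4. The array labelled β-catΔEx3:Myc replicate 3 lay between these arrays, at 9.02, with β-catΔEx3 at 28.5 to 52.3 and the other β-catΔEx3:Myc arrays at -72.2 to -29.7.

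**Figure D1:**
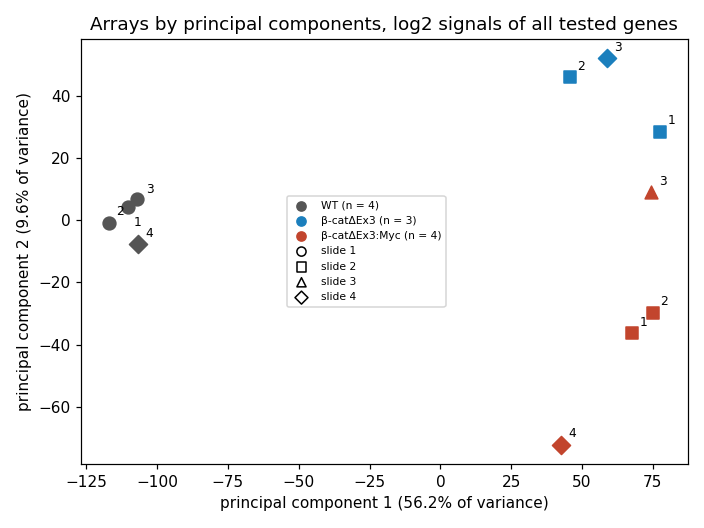
Scores of the 11 arrays on the first and second principal components (arbitrary units, share of the variance on each axis), coloured by group. WT arrays lie at -117.1 to -106.8 on the first component and the mutant arrays at 42.6 to 77.5.

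The transcripts targeted by the models were examined first. The signal of Ctnnb1, which encodes β-catenin, was not called different between WT livers and β-catΔEx3 or β-catΔEx3:Myc livers, with log2 fold changes of -0.17 ± 0.15 (adjusted p = 0.427) and -0.17 ± 0.14 (adjusted p = 0.351). The only Ctnnb1 probe cannot be placed relative to exon 3 from the files and may not report its deletion. Whether the only Myc probe reports the Myc that the model expresses cannot be told from the files either. Myc had a mean log2 signal over the upper quartile of 0.47 ± 1.26 (SD, n = 4) in WT livers, 1.97 ± 0.53 (SD, n = 3) in β-catΔEx3 livers and 3.83 ± 1.17 (SD, n = 4) in β-catΔEx3:Myc livers. It was higher on all 4 β-catΔEx3:Myc arrays than on all 4 WT arrays, by 10.3-fold (log2FC 3.36 ± 0.68, adjusted p = 0.00286, blocked 5.19 ± 1.13 with adjusted p = 0.0365). The log2FC of Myc was 3.97 without WT replicate 1. Between β-catΔEx3 and WT livers the difference was not called (log2FC 1.5 ± 0.73, adjusted p = 0.132), but it was without WT replicate 1, at 2.11 with adjusted p = 0.0254. All 4 β-catΔEx3:Myc arrays had more Myc than all 3 β-catΔEx3 arrays, without reaching the threshold (log2FC 1.86 ± 0.73, adjusted p = 0.401), and the difference was 2.90 within slide 4 and 1.97 within slide 2. Nfe2l2, which encodes the oxidative stress regulator Nrf2, was not called in any comparison, with log2 fold changes of -0.18, -0.33 and -0.16.

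To find the changes that came with mutant β-catenin alone, β-catΔEx3 livers were compared with WT livers. Of 22283 genes and unnamed transcripts tested, 4858 were higher and 3426 lower, and of these 2302 and 2341 changed at least 2-fold. The groups did not overlap for 43.7% of the genes, where chance gives 5.71%. The excess of increases depended on the scaling and turned to 3414 higher and 4657 lower with the 75th percentile over probes detected on all arrays. With slide as a block 947 were higher and 870 lower, 1647 of them called with the same sign in both fits, and the median standard error rose from 0.244 to 0.36. Leaving out any single array moved the fold of 12 of the 45 called genes named here by over 1.5 times, without changing a direction.

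Among the largest increases were genes of glutathione conjugation and oxidative defence. The glutathione transferases Gsta1 (2964-fold, log2FC 11.53 ± 0.65, blocked 9.67 ± 0.88) and Gsta2 (298-fold, log2FC 8.22 ± 0.51, blocked 6.98 ± 0.76) rose. The log2FC of Gsta1 was 10.92 without WT replicate 3. So did the carbonyl reductase Cbr3 (376-fold, log2FC 8.55 ± 0.84, blocked 7.6 ± 1.27) and the glutathione peroxidase Gpx2 (log2FC 8.13 ± 0.68, blocked 7.35 ± 1.1). Gsta1 and Gsta2 are close relatives, so their probes may share signal. The cystine transporter Slc7a11 (at least 95.8-fold, normexp 21.1-fold) and the exporter Abcc4 (log2FC 7.72 ± 0.52, blocked 7.58 ± 0.75) rose as well. Of the Nrf2 targets, 29 of 33 were higher and 1 lower (also adjusted over the list alone, camera adjusted p = 1.77e-13, 0.419 estimated).

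The estrogen sulfotransferase Sult1e1 (1153-fold, log2FC 10.17 ± 0.94, blocked 8.92 ± 1.57), the secreted semaphorin Sema3b (273-fold, log2FC 8.09 ± 0.39, blocked 7.31 ± 0.58), the pluripotency-associated Dppa5a (at least 95.0-fold, normexp 21.6-fold) and the membrane protein gene Lrtm2 (at least 83.2-fold, normexp 18.1-fold) were among the 10 largest increases that met the criteria for naming. The log2FC of Sult1e1 was 9.33 without WT replicate 1. Sult1e1 and Sema3b were above background on 3 of the 4 WT arrays, so their folds are less certain. For each of the genes among the 10 largest increases or decreases, all 3 β-catΔEx3 arrays lay on the same side of all 4 WT arrays. The rule for naming required this, so it adds no support.

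Targets and feedback regulators of Wnt signalling rose, among them Sp5 (8.43-fold, log2FC 3.08 ± 0.30, blocked 2.79 ± 0.56), the stem cell receptor Lgr5 (4.78-fold, log2FC 2.26 ± 0.20, blocked 2.04 ± 0.36) and Axin2 (log2FC 2.15 ± 0.68, blocked 1.54 ± 1.09 with adjusted p = 0.401). Axin2 was above background on 1 of the 4 WT arrays, so the size of its change is uncertain, and it also lost its call without WT replicate 2 (0.0743), WT replicate 3 (0.0733), β-catΔEx3 replicate 2 (0.0759) or β-catΔEx3 replicate 3 (0.103), given as adjusted p. Of the Wnt feedback targets, 8 of 14 were higher and 1 lower (also adjusted over the list alone, camera adjusted p = 0.0265, 0.524 estimated and 0.0641 with slide as a block). For the Wnt feedback targets the adjusted p was 0.0849 without β-catΔEx3 replicate 2. Hepatocytes around the central vein normally receive the Wnt signal, and their genes rose, such as Oat (18.2-fold, log2FC 4.19 ± 0.34, blocked 3.23 ± 0.46), the ammonia transporter Rhbg (15.7-fold, log2FC 3.98 ± 0.26, blocked 3.43 ± 0.26) and the glutamate transporter Slc1a2 (15.5-fold, log2FC 3.96 ± 0.30, blocked 3.33 ± 0.37). The perivenous list had 10 of 19 genes higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.00381, 0.556 estimated and 0.0705 with slide as a block). Genes of periportal hepatocytes fell, with Cyp2f2 (183-fold, log2FC -7.52 ± 1.04, blocked -7.6 ± 1.97 with adjusted p = 0.0594) and Hal (19.3-fold, log2FC -4.27 ± 0.63, blocked -4.74 ± 1.21 with adjusted p = 0.0577) as examples. The log2FC of Cyp2f2 was -8.47 without β-catΔEx3 replicate 2 and -6.63 without β-catΔEx3 replicate 3. The log2FC of Hal was -5.06 without β-catΔEx3 replicate 1. The periportal list had 1 of 21 genes higher and 10 lower (2 and 11 adjusted over the list alone, camera adjusted p = 0.00181, 0.524 estimated).

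**Figure D2:**
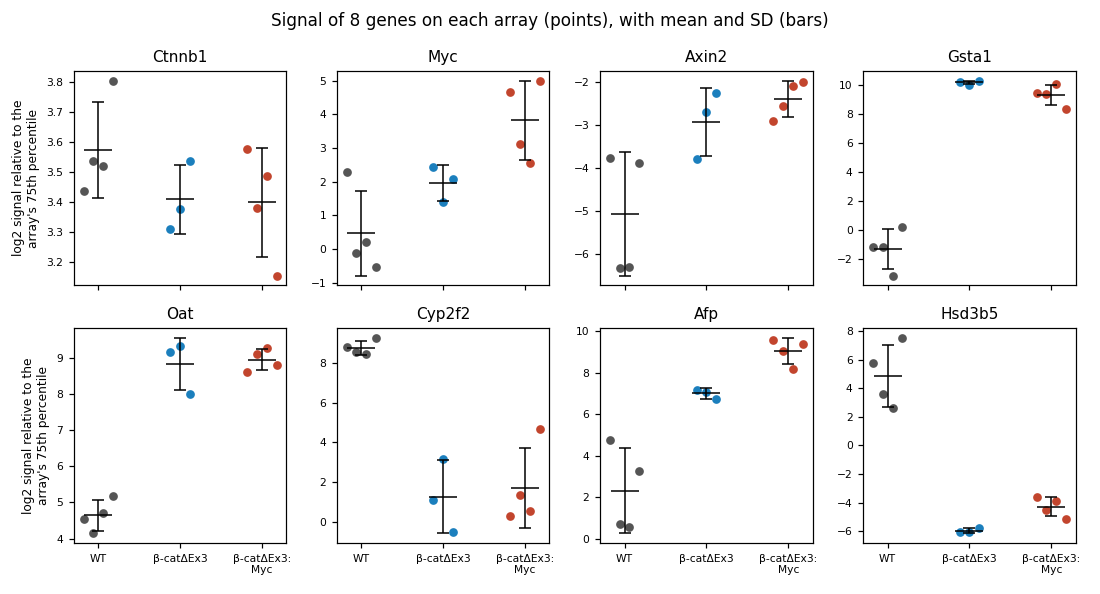
Log2 signal over the array's upper quartile for selected genes on each of the 11 arrays (points, one panel per gene with its own axis), with group means and SD (bars). Gsta1 is higher on every mutant array than on every WT array.

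Genes with male-biased expression in the liver fell, and their list had the lowest median of all lists. The steroid dehydrogenase Hsd3b5 (at least 815-fold, normexp 99.1-fold) and the major urinary protein genes fell, with Mup3 (927-fold, log2FC -9.86 ± 0.61, blocked -10.81 ± 0.72) as the most changed of 6 Mup genes among the 10 largest decreases. Mup genes are near-identical, so a probe may report several of them. The largest decrease was in Serpina4-ps1 (at least 6215-fold, normexp 811-fold), and Wfdc21 (928-fold, log2FC -9.86 ± 0.63, blocked -9.75 ± 0.91) and the esterase Ces3b (205-fold, log2FC -7.68 ± 0.50, blocked -8.58 ± 0.78) fell too. The male-biased list had 2 of 18 genes higher and 13 lower (also adjusted over the list alone, camera adjusted p = 7.5e-06, 0.52 estimated). The female-biased list had 2 of 18 genes higher and 5 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.636). For the female-biased liver genes the adjusted p was 0.0441 without WT replicate 4. The list was lower without that array, and its median log2FC of -0.261 turned to 1.97 with slide as a block.

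Metabolic lists were examined next. Of the mature hepatocyte genes, 3 of 25 were higher and 8 lower (also adjusted over the list alone, camera adjusted p = 0.00498, 0.556 estimated). Cyp8b1 (7.61-fold, log2FC -2.93 ± 0.44, blocked -3.23 ± 0.33) was an example. Fatty acid synthesis fell, with Pnpla3 (36.9-fold, log2FC -5.21 ± 0.61, blocked -3.50 ± 0.76) and Srebf1 (9.18-fold, log2FC -3.20 ± 0.48, blocked -3.69 ± 0.85). The log2FC of Srebf1 was -3.80 without β-catΔEx3 replicate 2. Pnpla3 was above background on 1 of the 3 β-catΔEx3 arrays. The list had 1 of 16 genes higher and 8 lower (1 and 11 adjusted over the list alone, camera adjusted p = 0.000136, 0.52 estimated). Glycolysis genes included the glucose transporter Slc2a1 (9.96-fold, log2FC 3.31 ± 0.36, blocked 2.53 ± 0.62 with adjusted p = 0.0521) and Aldoa (5.21-fold, log2FC 2.38 ± 0.25, blocked 2.30 ± 0.46) among the increases. Of the glycolysis genes, 10 of 18 were higher and 3 lower (also adjusted over the list alone, camera adjusted p = 0.133). In fatty acid oxidation Pdk4 (12.7-fold, log2FC 3.67 ± 0.21, blocked 3.96 ± 0.30) rose. Of the fatty acid oxidation genes, 3 of 21 were higher and 2 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.694). The organic anion transporter Slco1a1 (118-fold, log2FC -6.89 ± 0.68, blocked -8.61 ± 1.11) fell. The bile acid list had 6 of 21 genes higher and 8 lower (also adjusted over the list alone, camera adjusted p = 0.537). The cytochrome P450 list had 6 of 27 genes higher and 5 lower (7 and 5 adjusted over the list alone, camera adjusted p = 0.961). Cholesterol synthesis had 1 of 20 genes higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.626). For the cholesterol synthesis genes the adjusted p was 4.97e-10 without β-catΔEx3 replicate 1.

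Ribosome biogenesis genes rose, and few cell cycle genes were called. Mrto4 (2.81-fold, log2FC 1.49 ± 0.15, blocked 1.37 ± 0.21) and Srm (2.77-fold, log2FC 1.47 ± 0.20, blocked 1.71 ± 0.35) were ribosome biogenesis genes that rose. Their list had 18 of 30 genes higher and 0 lower (22 and 0 adjusted over the list alone, camera adjusted p = 2.14e-06, 0.52 estimated). The cell cycle list had 2 of 27 genes higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.76). For the cell cycle genes the adjusted p was 0.0425 without β-catΔEx3 replicate 2. Among fetal liver and hepatoblast genes Ly6d (87.9-fold, log2FC 6.46 ± 0.62, blocked 7.67 ± 1.05), the imprinted RNA Meg3 (57.5-fold, log2FC 5.84 ± 0.83, blocked 5.97 ± 1.20) and α-fetoprotein Afp (25.9-fold, log2FC 4.69 ± 0.88, blocked 3.63 ± 1.65 with adjusted p = 0.205) rose. The log2FC of Ly6d was 5.77 without β-catΔEx3 replicate 1 and 7.14 without β-catΔEx3 replicate 2. The log2FC of Afp was 5.51 without WT replicate 1 and 4.10 without WT replicate 3. Of the fetal liver genes, 7 of 26 were higher and 2 lower (also adjusted over the list alone, camera adjusted p = 0.617). The biliary list had 3 of 16 genes higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.727). Of the p53 targets, 5 of 17 were higher and 2 lower (also adjusted over the list alone, camera adjusted p = 0.225 and 0.0468 with slide as a block). The most changed of them was Gdf15 (10.9-fold, log2FC 3.45 ± 0.54, blocked 3.15 ± 0.85 with adjusted p = 0.065). The Atf4 and unfolded protein response list had 5 of 21 genes higher and 7 lower (6 and 9 adjusted over the list alone, camera adjusted p = 0.351). Asns (log2FC 3.41 ± 0.61, blocked 3.87 ± 1.03 with adjusted p = 0.0628) and Atf3 (8.77-fold, log2FC 3.13 ± 0.55, blocked 4.71 ± 0.79) were among those that rose. The log2FC of Asns was 4.06 without β-catΔEx3 replicate 2 and 2.83 without β-catΔEx3 replicate 3.

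Most lists of immune cells and of the immune response had more lower than higher genes. The acute phase list had 2 of 22 genes higher and 11 lower (2 and 12 adjusted over the list alone, camera adjusted p = 0.00269, 0.377 estimated). Its members Lcn2 (13.1-fold, log2FC 3.71 ± 0.50, blocked 4.48 ± 0.84) and Orm3 (27.5-fold, log2FC 4.78 ± 0.63, blocked 4.61 ± 1.25 with adjusted p = 0.0651) rose. The log2FC of Orm3 was 4.12 without WT replicate 1. The interferon-response list had 1 of 18 genes higher and 16 lower (also adjusted over the list alone, camera adjusted p = 5.57e-06, 0.524 estimated). Iigp1 (20.7-fold, log2FC -4.37 ± 0.44, blocked -3.90 ± 0.77) fell the most of these. The inflammatory cytokine and chemokine list had 0 of 13 genes higher and 3 lower (also adjusted over the list alone, camera adjusted p = 0.00693, 0.524 estimated and 0.225 with slide as a block). Il1b (at least 11.9-fold, normexp 2.47-fold) was lower, a call that was lost with slide as a block. The macrophage list had 3 of 19 genes higher and 12 lower (also adjusted over the list alone, camera adjusted p = 0.00273, 0.564 estimated and 0.16 with slide as a block). Marco (15.3-fold, log2FC -3.94 ± 0.91, blocked -4.59 ± 1.24 with adjusted p = 0.0647) was lower and Gpnmb (at least 26.4-fold, normexp 6.67-fold) higher. The log2FC of Marco was -4.57 without WT replicate 3 and -4.58 without β-catΔEx3 replicate 3. Lymphocyte markers had 0 of 16 genes higher and 12 lower (also adjusted over the list alone, camera adjusted p = 6.19e-06, 0.377 estimated). Ms4a1 (at least 9.03-fold, normexp 2.07-fold) was lower, and its call was lost with slide as a block. The erythroid list had 1 of 15 genes higher and 4 lower (also adjusted over the list alone, camera adjusted p = 0.0302, 0.625 estimated). For the erythroid markers the adjusted p was 0.0974 without WT replicate 4 and 0.0514 without β-catΔEx3 replicate 1. Neutrophil markers had 1 of 12 genes higher and 1 lower (also adjusted over the list alone, camera adjusted p = 0.0603). For the neutrophil markers the adjusted p was 0.042 without WT replicate 3, 0.0145 without β-catΔEx3:Myc replicate 3, 0.0348 without β-catΔEx3:Myc replicate 4 and 0.0226 without β-catΔEx3 replicate 2. Pancreatic acinar markers had 0 of 9 genes higher and 1 lower (also adjusted over the list alone, camera adjusted p = 0.331). Of the stellate cell and matrix genes, 0 of 23 were higher and 9 lower (0 and 10 adjusted over the list alone, camera adjusted p = 0.000129, 0.52 estimated and 0.27 with slide as a block). Of the endothelial markers, 0 of 20 were higher and 11 lower (0 and 12 adjusted over the list alone, camera adjusted p = 3.75e-05, 0.524 estimated).

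The same question was asked of livers labelled as carrying Myc besides mutant β-catenin, by comparing β-catΔEx3:Myc with WT livers. Here 5549 genes were higher and 3846 lower, 2514 and 2584 of them at least 2-fold, and the groups did not overlap for 42.2% of genes (2.86% by chance). Over probes detected on all arrays the balance turned to 4435 higher and 4740 lower. With slide as a block 945 were higher and 987 lower, 1758 called with the same sign in both fits, and the median standard error rose from 0.226 to 0.36. For 11 of the 27 called genes named in this comparison the fold moved by over 1.5 times when some single array was left out, without changing a direction. The changes were largely those of β-catΔEx3 livers. In both comparisons 6996 genes were called in the same direction and 9 in opposite directions, where independent calls would give 1801. Both comparisons use the same WT arrays, which by itself makes their changes alike. In 20 simulations with no change, sharing the WT arrays gave a correlation of 0.464 across genes and a covariance of 0.0594, against 0.896 and 1.27 in the data, and 0 genes shared. When each comparison was given 2 of the 4 WT arrays of its own, in all 6 ways, 2253 to 3010 genes were called in the same direction in both, with correlations of 0.797 to 0.849. Genes are not independent replicates in these correlations. In every such split both comparisons still hold WT arrays of slide 1, which has no mutant array. The splits therefore remove the shared arrays but not a shared effect of that slide.

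Oxidative defence genes were again among the largest increases, with Gsta1 (1616-fold, log2FC 10.66 ± 0.60, blocked 8.55 ± 0.88), Gsta2 (188-fold, log2FC 7.56 ± 0.48, blocked 6.12 ± 0.76) and Cbr3 (173-fold, log2FC 7.43 ± 0.78, blocked 6.09 ± 1.27). The log2FC of Gsta1 was 10.04 without WT replicate 3. The log2FC of Cbr3 was 8.41 without β-catΔEx3:Myc replicate 4. Mgst2 (161-fold, log2FC 7.33 ± 0.52, blocked 7.35 ± 0.92) and Sult1e1 (852-fold, log2FC 9.73 ± 0.87, blocked 8.88 ± 1.57) also rose. The log2FC of Sult1e1 was 8.90 without WT replicate 1. Of the Nrf2 targets, 27 of 33 were higher and 2 lower (29 and 2 adjusted over the list alone, camera adjusted p = 4.08e-10, 0.52 estimated). The Wnt feedback targets had 9 of 14 genes higher and 1 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.00745, 0.52 estimated). Sp5 (8.88-fold, log2FC 3.15 ± 0.28, blocked 2.89 ± 0.56) and Axin2 (log2FC 2.69 ± 0.63, blocked 1.98 ± 1.09 with adjusted p = 0.281) rose, the latter with the same limit at the background. The perivenous list had 10 of 19 genes higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.0155, 0.556 estimated and 0.22 with slide as a block). Oat (19.9-fold, log2FC 4.32 ± 0.31, blocked 3.25 ± 0.46) rose. The periportal list had 3 of 21 genes higher and 9 lower (also adjusted over the list alone, camera adjusted p = 0.016, 0.556 estimated and 0.0553 with slide as a block). Cyp2f2 (133-fold, log2FC -7.06 ± 0.96, blocked -6.75 ± 1.97 with adjusted p = 0.0766) fell. The log2FC of Cyp2f2 was -8.04 without β-catΔEx3:Myc replicate 4. Male-biased genes fell, with Hsd3b5 (576-fold, log2FC -9.17 ± 0.87, blocked -12.18 ± 1.20) and Mup3 (394-fold, log2FC -8.62 ± 0.57, blocked -9.44 ± 0.72). The log2FC of Hsd3b5 was -9.92 without WT replicate 3 and -8.29 without WT replicate 4. The male-biased list had 1 of 18 genes higher and 11 lower (also adjusted over the list alone, camera adjusted p = 1.49e-05, 0.52 estimated). Hsd3b5 was above background on 2 of the 4 β-catΔEx3:Myc arrays. The female-biased list had 4 of 18 genes higher and 4 lower (also adjusted over the list alone, camera adjusted p = 0.533). For the female-biased liver genes the adjusted p was 0.0238 without WT replicate 4. The list was lower without that array, and its median of -0.889 turned to 1.57 with slide as a block. Serpina4-ps1 (at least 4680-fold, normexp 855-fold) was again the largest decrease. The complement gene C9 (256-fold, log2FC -8.00 ± 0.96, blocked -8.06 ± 1.42) was lower, though above background on 1 of the 4 β-catΔEx3:Myc arrays. The log2FC of C9 was -9.01 without β-catΔEx3:Myc replicate 4.

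Among fetal liver genes Afp (log2FC 6.75 ± 0.82, blocked 5.97 ± 1.65 with adjusted p = 0.0671), Bex1 (83.8-fold, log2FC 6.39 ± 0.84, blocked 6.50 ± 0.43) and Dlk1 (82.8-fold, log2FC 6.37 ± 1.37, blocked 7.70 ± 1.77) were higher than in WT livers. The log2FC of Afp was 7.56 without WT replicate 1 and 6.16 without WT replicate 3. The log2FC of Bex1 was 7.44 without β-catΔEx3:Myc replicate 3. The log2FC of Dlk1 was 7.04 without WT replicate 1, 5.65 without WT replicate 2, 7.83 without β-catΔEx3:Myc replicate 3 and 5.50 without β-catΔEx3:Myc replicate 4. Dlk1 was above background on 3 of the 4 WT arrays, and its groups overlapped. Of the fetal liver genes, 12 of 26 were higher and 3 lower (also adjusted over the list alone, camera adjusted p = 0.043, 0.524 estimated). For the fetal liver and hepatoblast genes the adjusted p was 0.0754 without WT replicate 4, 0.0665 without β-catΔEx3:Myc replicate 1, 0.0728 without β-catΔEx3:Myc replicate 4 and 0.0529 without β-catΔEx3 replicate 3. Ribosome biogenesis had 22 of 30 genes higher and 0 lower (25 and 0 adjusted over the list alone, camera adjusted p = 4.96e-06, 0.52 estimated). Srm (2.69-fold, log2FC 1.43 ± 0.18, blocked 1.74 ± 0.35) was among them. The cell cycle list had 1 of 27 genes higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.94 and 0.0407 with slide as a block). Mature hepatocyte genes had 3 of 25 genes higher and 10 lower (3 and 11 adjusted over the list alone, camera adjusted p = 0.00379, 0.556 estimated). Fatty acid synthesis fell, with Scd1 (60.2-fold, log2FC -5.91 ± 0.94, blocked -4.88 ± 1.97 with adjusted p = 0.16). Its list had 0 of 16 genes higher and 13 lower (also adjusted over the list alone, camera adjusted p = 3.66e-07, 0.419 estimated). Glycolysis had 10 of 18 genes higher and 3 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.113). Fatty acid oxidation had 4 of 21 genes higher and 3 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.948). Pdk4 (17.2-fold, log2FC 4.11 ± 0.20, blocked 4.49 ± 0.30) was higher. Cholesterol synthesis had 1 of 20 genes higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.915). The bile acid list had 7 of 21 genes higher and 4 lower (also adjusted over the list alone, camera adjusted p = 0.872). The cytochrome P450 list had 8 of 27 genes higher and 4 lower (also adjusted over the list alone, camera adjusted p = 0.94). The biliary list had 2 of 16 genes higher and 3 lower (also adjusted over the list alone, camera adjusted p = 0.295). Spp1 (5.63-fold, log2FC -2.49 ± 0.45, blocked -2.07 ± 0.59 with adjusted p = 0.074) was lower. The p53 list had 7 of 17 genes higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.17 and 0.0226 with slide as a block). Cdkn1a (3.86-fold, log2FC 1.95 ± 0.44, blocked 3.47 ± 0.45) was higher. The Atf4 list had 6 of 21 genes higher and 9 lower (6 and 10 adjusted over the list alone, camera adjusted p = 0.288). Asns (21-fold, log2FC 4.39 ± 0.56, blocked 5.09 ± 1.03) was higher.

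Endothelial, stellate and lymphocyte genes fell. Of the endothelial markers, 0 of 20 were higher and 17 lower (also adjusted over the list alone, camera adjusted p = 1.9e-10, 0.419 estimated). Clec4g (6.39-fold, log2FC -2.68 ± 0.22, blocked -2.60 ± 0.44) fell. Stellate cell and matrix genes had 0 of 23 genes higher and 18 lower (0 and 19 adjusted over the list alone, camera adjusted p = 1.53e-09, 0.377 estimated). Lum (6.75-fold, log2FC -2.75 ± 0.25, blocked -2.03 ± 0.32) fell. The macrophage list had 3 of 19 genes higher and 13 lower (3 and 14 adjusted over the list alone, camera adjusted p = 0.000301, 0.556 estimated and 0.0723 with slide as a block). Adgre1 (15-fold, log2FC -3.90 ± 0.57, blocked -2.90 ± 0.94 with adjusted p = 0.0976) fell. The lymphocyte list had 1 of 16 genes higher and 13 lower (also adjusted over the list alone, camera adjusted p = 1.25e-05, 0.377 estimated). The interferon list had 1 of 18 genes higher and 9 lower (also adjusted over the list alone, camera adjusted p = 0.001, 0.556 estimated and 0.205 with slide as a block). The inflammatory list had 0 of 13 genes higher and 5 lower (also adjusted over the list alone, camera adjusted p = 0.00768, 0.524 estimated and 0.423 with slide as a block). The acute phase list had 3 of 22 genes higher and 12 lower (3 and 13 adjusted over the list alone, camera adjusted p = 0.00147, 0.377 estimated). Neutrophil markers had 4 of 12 genes higher and 1 lower (also adjusted over the list alone, camera adjusted p = 0.131 and 0.00477 with slide as a block). For the neutrophil markers the adjusted p was 0.00552 without β-catΔEx3:Myc replicate 3. Chil3 (10.6-fold, log2FC 3.41 ± 0.80, blocked 4.2 ± 0.84) was higher. The log2FC of Chil3 was 4.2 without β-catΔEx3:Myc replicate 3 and 2.67 without β-catΔEx3:Myc replicate 4. The erythroid list had 2 of 15 genes higher and 2 lower (2 and 1 adjusted over the list alone, camera adjusted p = 0.939). The pancreatic list had 0 of 9 genes higher and 1 lower (also adjusted over the list alone, camera adjusted p = 0.891).

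**Figure D3:**
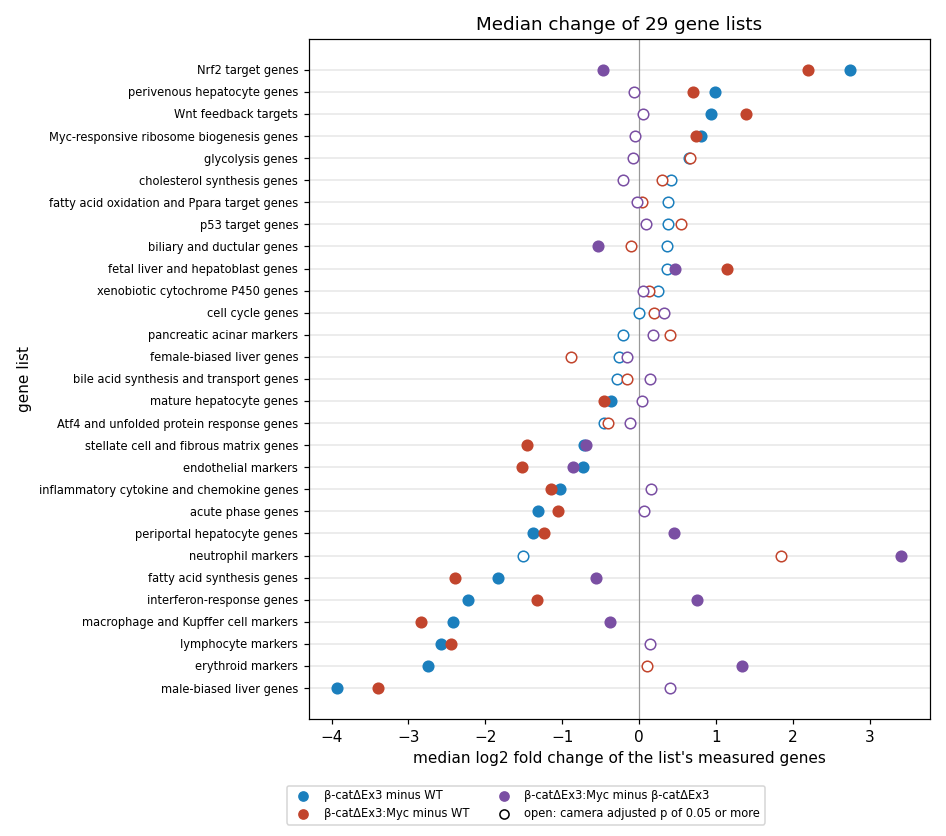
Median log2 fold change of the measured genes of 29 lists in each comparison, with fitted values for genes at the background. Filled points have a camera adjusted p under 0.05. The Nrf2 targets lie at 2.74 and 2.2 and the male-biased genes at -3.93 and -3.4 in β-catΔEx3 and β-catΔEx3:Myc livers against WT (-3.39 and -3.21 with genes at the background set to their bound).

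To isolate what the Myc group added, β-catΔEx3:Myc livers were compared with β-catΔEx3 livers. Only 28 genes were higher and 46 lower, 28 and 43 of them at least 2-fold, and 2292 genes had an unadjusted p under 0.05. The groups did not overlap for 8.17% of genes, where chance gives 5.71%. The balance of directions turned with the scaling, at 33 higher and 9 lower without scaling, 31 and 98 with median scaling and 20 and 15 with the 75th percentile over probes detected on all arrays. With slide as a block, which sets aside β-catΔEx3:Myc replicate 3 because it is alone on its slide, 114 were higher and 70 lower, and 54 genes were called in both fits. With slides 2 and 4 only and the same block, 1 was higher and 0 lower. The main counts of 28 and 46 moved by over 1.5 times when single arrays were left out. They were 115 and 66 without β-catΔEx3:Myc replicate 3, 40 and 75 without β-catΔEx3 replicate 1, 30 and 23 without β-catΔEx3 replicate 2 and 6 and 4 without β-catΔEx3 replicate 3. Without β-catΔEx3:Myc replicate 2 they were 9 and 7, without β-catΔEx3:Myc replicate 4 they were 10 and 12, and without WT replicates 1, 2 and 3 they were 9 and 6, 18 and 16, and 16 and 18.

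The called increases included transcripts of myeloid cells and of megakaryocytes, the cells that shed platelets. Ctsg (16.9-fold, log2FC 4.08 ± 0.65, blocked 4.73 ± 0.47), a granule protease of immature neutrophils, and Ms4a3 (at least 4.13-fold, normexp 1.55-fold with adjusted p = 0.234) were higher. The log2FC of Ctsg was 4.73 without β-catΔEx3:Myc replicate 3. Of the platelet genes, Ppbp (16.3-fold, log2FC 4.03 ± 0.57, blocked 4.19 ± 0.68), Gp1ba (at least 7.05-fold, normexp 1.87-fold) and Rgs18 (at least 6.90-fold, normexp 1.71-fold) were higher. The log2FC of Ppbp was 3.12 without β-catΔEx3 replicate 1 and 4.62 without β-catΔEx3 replicate 2. Zfp949 (8.6-fold, log2FC 3.10 ± 0.28, blocked 3.23 ± 0.32) and Tbc1d30 (8.71-fold, log2FC 3.12 ± 0.38, blocked 3.01 ± 0.27) also rose. Decreases included the peptidase Mme (27.1-fold, log2FC -4.76 ± 0.82, blocked -4.25 ± 0.89 with adjusted p = 0.101), the serpin Serpina3i (13.3-fold, log2FC -3.73 ± 0.40, blocked -3.60 ± 0.46) and the ferroxidase Heph (4.09-fold, log2FC -2.03 ± 0.23, blocked -1.98 ± 0.23). The log2FC of Mme was -5.57 without β-catΔEx3:Myc replicate 1. Ctsg was above background on 1 and Ppbp on 2 of the 3 β-catΔEx3 arrays, and Mme on 1 of the 4 β-catΔEx3:Myc arrays. For each of these genes all 4 β-catΔEx3:Myc arrays lay on the same side of all 3 β-catΔEx3 arrays. The rule for naming the largest changes required this, so it adds no support.

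Rgs18, Gp1ba, Zfp949, Serpina3i and Heph stayed called when any single array was left out. Tbc1d30 was not called without β-catΔEx3 replicate 3 (adjusted p = 0.0855). Ms4a3 was not called without WT replicate 1 (0.0538), β-catΔEx3:Myc replicate 2 (0.0549), β-catΔEx3 replicate 2 (0.0549) or β-catΔEx3 replicate 3 (0.13). Ppbp was not called without WT replicate 1 (0.0544), β-catΔEx3:Myc replicate 2 (0.0549), β-catΔEx3:Myc replicate 4 (0.0572) or β-catΔEx3 replicate 3 (0.0855). Ctsg was called with all arrays and without β-catΔEx3:Myc replicate 3, with adjusted p of 0.0503 to 0.169 without each of the others. Mme was called without β-catΔEx3:Myc replicate 1, β-catΔEx3:Myc replicate 3 or β-catΔEx3 replicate 1, with adjusted p of 0.0626 to 0.204 without each of the others. The fold of 3 of the 11 called genes named in this comparison moved by over 1.5 times without some single array, and no direction changed.

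Lists of cell type markers gave the direction in which cell-type transcripts shifted. Neutrophil markers had 1 of 12 genes higher and 0 lower (10 and 1 adjusted over the list alone, camera adjusted p = 5.75e-10, 0.377 estimated). Their median log2FC was 3.41, and it was 5.36 within slide 4 and 3.67 within slide 2. Endothelial markers had 0 of 20 genes higher and 1 lower (0 and 13 adjusted over the list alone, camera adjusted p = 1.32e-15, 0.377 estimated). Their median was -0.86, and it was -0.97 within slide 4 and -0.73 within slide 2. Tie1 (1.79-fold, log2FC -0.84 ± 0.14, blocked -0.82 ± 0.15 with adjusted p = 0.0722) was the endothelial gene called, and leaving out any of the 11 arrays ended its call (adjusted p of 0.0529 to 0.187). Stellate cell and matrix genes had 0 of 23 genes called (0 and 11 adjusted over the list alone, camera adjusted p = 1.35e-10, 0.377 estimated). Their median was -0.70, and it was -0.90 within slide 4 and -0.63 within slide 2. The erythroid list was higher, with 0 of 15 genes called (1 and 0 adjusted over the list alone, camera adjusted p = 6.41e-05, 0.52 estimated). Hba-a1 (log2FC 0.73 ± 0.92, adjusted p = 0.874, blocked 1.48 ± 0.76) was not called. The interferon list was higher, with 0 of 18 genes called (also adjusted over the list alone, camera adjusted p = 0.000163, 0.556 estimated). For the interferon-response genes the adjusted p was 0.0744 without β-catΔEx3:Myc replicate 4. The list's median was 0.747, and it was 2.11 within slide 4 and -0.104, of the other sign, within slide 2. The macrophage list was lower, with 0 of 19 genes called (also adjusted over the list alone, camera adjusted p = 0.0334, 0.735 estimated and 0.225 with slide as a block). For the macrophage and Kupffer cell markers the adjusted p was 0.601 without β-catΔEx3:Myc replicate 2, 0.302 without β-catΔEx3:Myc replicate 3, 0.0829 without β-catΔEx3 replicate 2 and 0.939 without β-catΔEx3 replicate 3. Without β-catΔEx3 replicate 3 the direction of the list turned. The lymphocyte list had 0 of 16 genes called (also adjusted over the list alone, camera adjusted p = 0.533).

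In the lists of other programmes 0 genes were called over all genes tested. Fetal liver genes were higher, with 0 of 26 genes called (8 and 2 adjusted over the list alone, camera adjusted p = 0.0022, 0.419 estimated). Biliary genes were lower, with 0 of 16 genes called (0 and 2 adjusted over the list alone, camera adjusted p = 0.000172, 0.377 estimated). Nrf2 targets were lower than in β-catΔEx3 livers, with 0 of 33 genes called (also adjusted over the list alone, camera adjusted p = 6.58e-07, 0.524 estimated). Their median was -0.47, and it was -1.37 within slide 4 and -0.36 within slide 2. The mean log2 deviation of the list's genes was -0.017 on β-catΔEx3:Myc replicate 4 and 0.787 to 1.494 on the other β-catΔEx3:Myc arrays, with β-catΔEx3 at 1.164 to 1.521. Without β-catΔEx3:Myc replicate 4 the adjusted p was 0.000427, and it was 0.197 with fry. Between the mutant groups fry also ended the calls of the fetal (adjusted p = 0.0523), erythroid (0.14), fatty acid synthesis (0.162), interferon (0.303), periportal (0.345) and macrophage lists (0.566). It kept those of the neutrophil (0.0135), endothelial (0.00815), stellate (0.0112) and biliary lists (0.035). Fatty acid synthesis was lower, with 0 of 16 genes called (also adjusted over the list alone, camera adjusted p = 0.000116, 0.52 estimated). For the fatty acid synthesis genes the adjusted p was 0.125 without β-catΔEx3 replicate 2. Periportal genes were higher, with 0 of 21 genes called (also adjusted over the list alone, camera adjusted p = 0.0265, 0.556 estimated). For the periportal hepatocyte genes the adjusted p was 0.096 without β-catΔEx3:Myc replicate 2, 0.166 without β-catΔEx3:Myc replicate 4 and 0.541 without β-catΔEx3 replicate 3. Ribosome biogenesis had 0 of 30 genes called (also adjusted over the list alone, camera adjusted p = 0.537). For the Myc-responsive ribosome biogenesis genes the adjusted p was 0.00321 without β-catΔEx3 replicate 2. The cell cycle list had 0 of 27 genes called (also adjusted over the list alone, camera adjusted p = 0.351). For the cell cycle genes the adjusted p was 0.00124 without β-catΔEx3:Myc replicate 2, 0.038 without β-catΔEx3:Myc replicate 3 and 1.68e-05 without β-catΔEx3 replicate 2. Wnt feedback targets had 0 of 14 genes called (1 and 0 adjusted over the list alone, camera adjusted p = 0.351). Perivenous genes had 0 of 19 genes called (also adjusted over the list alone, camera adjusted p = 0.295). For the perivenous hepatocyte genes the adjusted p was 0.015 without β-catΔEx3 replicate 3. Mature hepatocyte genes had 0 of 25 genes called (1 and 0 adjusted over the list alone, camera adjusted p = 0.939). The remaining lists were those of p53 targets, Atf4, acute phase, inflammation, pancreas, glycolysis, cholesterol synthesis, fatty acid oxidation, bile acids, cytochrome P450 and male- and female-biased genes. They had camera adjusted p from 0.157 to 0.995 and 0 called genes. Adjusted over the list alone, 2 acute phase genes were higher and 2 lower, 2 inflammatory genes lower, 2 pancreatic genes higher, and 2 bile acid genes higher and 1 lower, with 0 in the other lists. Without single arrays, cholesterol synthesis reached 1.47e-25 (without β-catΔEx3 replicate 1), fatty acid oxidation 0.0107 (without β-catΔEx3 replicate 3) and the pancreatic list 0.0331 (without β-catΔEx3:Myc replicate 2) and 0.0131 (without β-catΔEx3 replicate 2).

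**Figure D4:**
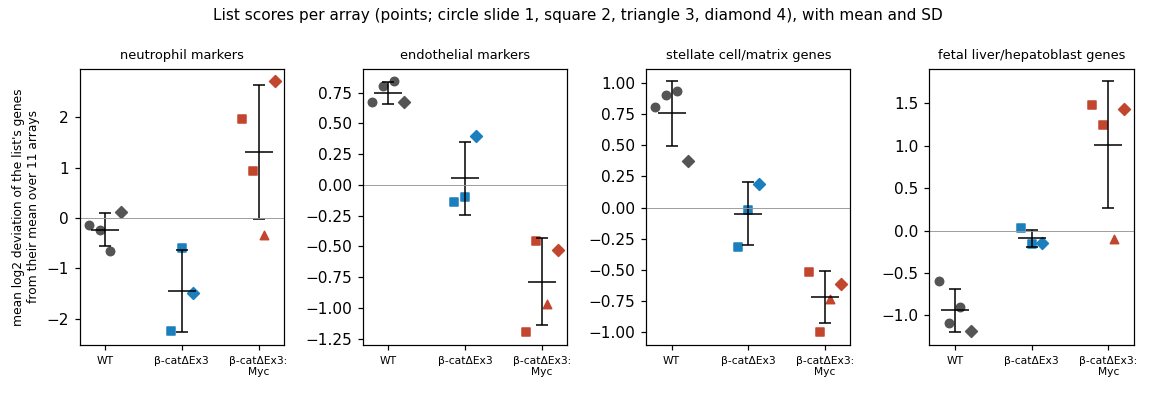
Mean log2 signal of the genes of selected lists on each of the 11 arrays, each gene first centred on its mean over the arrays (points), with group means and SD. Neutrophil markers are higher and endothelial markers lower in β-catΔEx3:Myc than in β-catΔEx3 livers on average.

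The list tests presumed a correlation of 0.01 between the genes of a list. With a correlation estimated for each list none of the 87 tests was called, and the lowest adjusted p was 0.377. The median, the mean and the tested direction did not share a sign for the Atf4 and cytochrome P450 lists in β-catΔEx3 livers, nor for these lists and the erythroid, pancreatic and bile acid lists in β-catΔEx3:Myc livers, each against WT. Between the mutant groups they differed in sign for the acute phase, inflammatory, cytochrome P450 and female-biased lists. Scaling the arrays in other ways kept the direction of every called list relative to other genes, but ended some calls and added others. The erythroid list in β-catΔEx3 livers against WT had an adjusted p of 0.0511 with quantile normalization, 0.12 with normexp background correction and 0.0985 with the 75th percentile taken over probes detected on all arrays. The fetal list in β-catΔEx3:Myc livers against WT had 0.0987 without scaling and 0.0524 with normexp. Between the mutant groups the macrophage list had 0.0524 to 0.142 under 4 such alternatives, and the periportal list 0.0987 without scaling and 0.0507 with the probes detected on all arrays. Calls were added for the neutrophil list in β-catΔEx3 livers against WT, at 0.044 with median scaling and 0.0378 without scaling, and for the male-biased list between the mutant groups, at 0.041 with median scaling.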

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

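The tests of slide, of a slide of its own, of the share of hepatocytes, of blood and of other splits of the arrays were chosen after the results were seen. The test of an array's position was written after that array had been seen near the other group and before the position was computed.

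In the groups of 4 arrays, an array was singled out when its gap to the nearest other array was too large a part of the group's range by Dixon's criterion at 95%. This held in 14 of 204 tests of the named genes and lists, and chance gives about 1 in 20. WT replicate 4, the only WT array on slide 4, accounted for 7 of them. Its log2 signal over the upper quartile was -5.83 for Dppa5a (others -6.62 to -6.59), -5.34 for Gp1ba (others -4.05 to -3.81) and 2.18 for Lum (others 2.93 to 2.97). All Dppa5a values lay below the lowest signal well above background on the WT arrays (-4.586 to -4.083), so that gap is one at the floor. The list scores of WT replicate 4, the mean log2 deviation of a list's genes from their mean over the arrays, were -0.415 for perivenous genes (others -0.84 to -0.79) and -0.887 for cell cycle genes (others 0.184 to 0.268). They were 1.75 for erythroid markers (others -0.1 to 0.11) and 0.176 for bile acid genes (others -0.142 to -0.112). WT replicate 1 had Aldoa at 6.87 (others 6.54 to 6.59) and a fatty acid oxidation score of 0.445 (others -0.425 to -0.313).

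Among β-catΔEx3:Myc arrays, replicate 4 had Cbr3 at 4.47 (others 8.06 to 8.58) and C9 at -2.29 (others -6.44 to -6.23), and replicate 1 had Gpnmb at 1.11 (others -0.232 to -0.0722). The array labelled replicate 3 had Bex1 at 0.972 (others 5 to 5.33) and a fetal liver score of -0.0981 (others 1.24 to 1.48).

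The number of genes called against WT was weighed first, since 3 of the 4 WT arrays lie on a slide of their own. Of the genes called without slide 4, 94.3% of 6896 in β-catΔEx3 and 91.4% of 9030 in β-catΔEx3:Myc livers had the same sign between the arrays of slide 4, where a difference between slides as the whole cause would give about 50%. With slide as a block 947 and 870 genes were still called in β-catΔEx3 and 945 and 987 in β-catΔEx3:Myc livers. Of the 35 splits of the arrays into groups of these sizes, fitted without slide, 1 gave as many genes in each comparison. This was the real one (8284 and 9395 genes, highest others 234 and 1). The smallest share these splits can give is 1 in 35, and they exchange arrays between slides. They argue against chance but do not exclude it, nor do they tell group from slide. The 234 came from setting WT replicates 1 to 3 apart from the other arrays. That split differs from the real one only by WT replicate 4, so it cannot tell an effect of slide 1 from the group difference. A part of the calls may still come from slide 1. Age, which the labels give only as a range for the mice of slide 1, stays open and untested.

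The array labelled β-catΔEx3:Myc replicate 3 lay between the mutant groups on the second principal component (9.02). It correlated best with β-catΔEx3:Myc replicate 2 (0.9819) and β-catΔEx3 replicate 1 (0.981). On an axis from the β-catΔEx3 mean (0) to the β-catΔEx3:Myc mean (1) its position was 0.386, within the β-catΔEx3 range of 0.0528 to 0.557 and below the other β-catΔEx3:Myc arrays at 0.798 to 0.995, so a wrong label or a liver with little Myc effect may explain it. Other values lay on both sides, with Myc at 2.55 (highest β-catΔEx3 array 2.44) and the scores of Wnt (0.831), endothelial (-0.965) and stellate genes (-0.729) beyond the β-catΔEx3 range towards β-catΔEx3:Myc arrays, but those of fetal (-0.0981), Nrf2 (1.49) and erythroid genes (-1.27) within it. Its neutrophil score (-0.343, highest β-catΔEx3 array -0.604) and its score for the later megakaryocyte list (0.475) also lay beyond that range. Its scores for the later lists of immature granulocyte (-0.807) and mature neutrophil genes (-0.265) lay within it. This array is the only one (1) on its slide and scan, so an effect of that slide cannot be told apart from one of the liver. No β-catΔEx3 array lay among the β-catΔEx3:Myc arrays as the partner an exchange would need. Of the 35 splits of the mutant arrays, fitted without slide, 2 called at least 74 genes, the real one with 74 and 1 other with 96. The other placed this array with the β-catΔEx3 arrays, so chance is not excluded. With slide as a block 114 genes were higher and 70 lower, but with slides 2 and 4 only and a block 1 was higher and 0 lower. No splits were run with a block.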

How the results depend on the processing

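The scaling over probes detected on all arrays and the block for scan date were chosen after the data were seen, and all other alternatives before. In the comparisons with WT, all 4 counts stayed within 1.5 times their value under quantile normalization, median scaling, no scaling, normexp, both filters, other handling of probes, array weights, the trended fit, the fit of 2 groups, the deposited matrix, the random slide block and both added alternatives. Without single arrays they were 3420 to 4914 higher and 2622 to 3489 lower in β-catΔEx3, and 4417 to 5779 higher and 3311 to 4006 lower in β-catΔEx3:Myc livers, with 5247 to 7076 shared calls.

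The settings that moved these counts were slide as a fixed block, slides 2 and 4 alone, and the thresholds. With slide as a fixed block 947 genes were higher and 870 lower in β-catΔEx3, 945 and 987 in β-catΔEx3:Myc, and 114 and 70 between the mutant groups, with 1294 shared calls. By its construction this fit sets WT replicates 1 to 3 aside, because their slide holds no other group, and β-catΔEx3:Myc replicate 3, which is alone. With slides 2 and 4 only and a block the counts were 176 and 138, 153 and 136, and 1 and 0, with 218 shared calls, from fewer arrays (limma, where the main fit had 2292 genes at an unadjusted p under 0.05 between the mutant groups). An adjusted p under 0.01 gave 2725 higher and 1988 lower in β-catΔEx3 and 3437 higher in β-catΔEx3:Myc, 6 higher and 4 lower between the mutant groups, and 3984 shared calls. Requiring a 2-fold change gave 2302 higher in β-catΔEx3, 2514 higher in β-catΔEx3:Myc and 3629 shared calls.

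The 28 higher and 46 lower genes between the mutant groups also moved under settings that left the counts against WT in place. They were 18 and 24 without a filter on dim probes, 43 and 70 with a filter by group, 6 and 3 with the 2 groups fitted alone and 46 and 70 with slide as a random block. Scan date as a block gave 110 higher. Lower genes numbered 98 with median scaling, 9 without scaling, 19 with array weights and 15 with the scaling over detected probes. The cause was not tested. Without single arrays the counts were 6 to 115 higher and 4 to 75 lower.

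The share of called genes that were higher moved with the scaling. It was 58.6% in β-catΔEx3 livers and 42.3% with the scaling over detected probes, and 59.1% in β-catΔEx3:Myc livers, 70.5% without scaling and 48.3% over detected probes. Between the mutant groups it was 37.8%, and 24% with median scaling, 78.6% without scaling and 57.1% over detected probes. The median log2 fold change of all genes was 0.10 and 0.13 against WT, shifted to -0.08 and -0.01 with the scaling over detected probes and to 0.32 in β-catΔEx3:Myc livers without scaling, and it was -0.12 between the mutant groups with median scaling.

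For named genes 2488 values stayed on their side of the threshold, 140 lost a call and 4 gained one (52 and 19 of the losses with slides 2 and 4 alone and with slide as a block). No called direction changed, but the sign of 15 values turned in genes that were not called (Ctnnb1, Nfe2l2, Hba-a1 and Csf3r). Normexp, run with an offset, lowered the log2 fold changes of dim genes, to 0.45 and 0.576 for Axin2 against WT and 0.903 for Gp1ba between the mutant groups. For lists 2113 tests stayed on their side, 134 of them with another direction and no call. Of the others 43 lost a call with an estimated correlation, 13 with slides 2 and 4 only, 11 with slide as a block and 10 with fry, and 39 gained one under some alternative. The tested direction reversed for the female-biased list against WT with slides 2 and 4 only, at adjusted p of 0.0265 in β-catΔEx3 and 0.0198 in β-catΔEx3:Myc livers, and for the macrophage list between the mutant groups without β-catΔEx3 replicate 3, at 0.939 (3.42e-05 to 0.939 without single arrays). The cause was not tested. Genes near the background limit what can be said, since 49.0% to 53.4% of the probes were well above it and folds of the others are bounds or uncertain.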

Other observations

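The tests of the share of hepatocytes, of blood and of slide, and the lists of complement, glutathione, megakaryocyte, granulocyte, imprinted and clock genes, were chosen after the data were seen.

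In both mutant livers the genes of the liver's zones shifted towards the perivenous side. Wnt feedback targets and perivenous genes rose and periportal genes fell, although the blocked fit ended the call of the perivenous list in both and of the Wnt list in β-catΔEx3 and the periportal list in β-catΔEx3:Myc livers. With an estimated correlation none of these list calls held in either group (0.52 to 0.556). Of the lists set before, the Nrf2 targets had the highest median change in both without slide as a block, though not in β-catΔEx3:Myc livers with it (0.419 and 0.52 with an estimated correlation), while Nfe2l2 itself was not called, and arrays do not measure its protein. Among lists added later, glutathione and NADPH enzymes outside the Nrf2 list had 12 of 17 genes higher and 0 lower in β-catΔEx3 livers (camera adjusted p = 0.00031) and 9 and 0 in β-catΔEx3:Myc livers (0.0057), and 0 were called between the mutant groups (lower, 0.0347). Complement and coagulation genes, which hepatocytes secrete, had 22 of 28 lower and 0 higher in both (1.17e-10 and 2.19e-10) and 0 called between the mutant groups (0.63). None of the lists added later was called with an estimated correlation (0.0755 to 0.96).

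Between the mutant groups, megakaryocyte and platelet genes had 5 of 14 higher in β-catΔEx3:Myc livers and 0 lower, with a median log2 fold change of 1.54 (camera adjusted p = 3.51e-12, 0.0755 with an estimated correlation). The genes of this list leave out those named in the report. The list was still chosen after those genes were seen on the same arrays, so it is not an independent test. Lists that split granulocyte genes by stage, in part from the neutrophil list, did not separate the stages. Immature granulocyte genes (8 measured, 0.00122) and mature neutrophil genes (6 measured, 0.000395) were both higher with 0 genes called (0.461 and 0.297 with an estimated correlation), with scores that differed by 1.87 ± 0.85 and 1.97 ± 0.81 (SE). Imprinted genes had 0 called between these groups (0.0347, 0.597 with an estimated correlation) and clock genes 0 of 14 (0.63). Against WT, in β-catΔEx3 and then β-catΔEx3:Myc livers, the adjusted p was 0.153 and 0.0141 (0.462 with an estimated correlation) for the megakaryocyte list, 0.373 and 0.457 for immature granulocytes, 0.329 and 0.453 for mature neutrophils, 0.919 and 0.184 for imprinted genes and 0.908 and 0.63 for clock genes.

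The rise of neutrophil markers in β-catΔEx3:Myc livers with a fall of endothelial and stellate markers was weighed against a lower share of hepatocytes, which would raise all of them. The neutrophil score rose by 2.77 ± 0.816 (SE) while the endothelial score fell by 0.841 ± 0.247 and the stellate score fell by 0.666 ± 0.179, which argues against that as the whole cause, and within both slides that hold both groups the directions were kept, by at least 0.631 in the list medians, which argues against slide. Blood left in the tissue stays open, since Hba-a1, an abundant red cell transcript, rose by 0.727 ± 0.92, a value that cannot be told apart from the neutrophil rise or from 0. The erythroid score rose by 1.89 ± 0.863 (SE), which cannot be told apart from the neutrophil rise either. Of its 15 genes, 6 were at the background on all arrays of the lower group. Of the 12 neutrophil genes 0 are in another list and 9 were above background on all WT arrays, and of the most abundant, named after their values were seen, S100a9 was at 0.61 ± 1.04 in β-catΔEx3, 3.97 ± 1.81 in β-catΔEx3:Myc and 2.68 ± 0.37 in WT livers (log2 signal, SD) and Csf3r differed by 0.09 ± 0.14 (SE). Age and tumour stage stay open and untested.

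Within-group differences stood out in some lists. The cholesterol synthesis score was -1.99 in β-catΔEx3 replicate 1 and 1.45 and 1.34 in the other β-catΔEx3 arrays. The male-biased score was 4.00 in WT replicate 4 and 0.776 to 2.43 in the other WT arrays, and its female-biased score was -2.37 with others at 0.0777 to 2.08. These lists follow sexual maturation, and no age is given for WT replicates 1 to 3 other than the range. Cell cycle scores ranged from -1.05 to 1.15 over the mutant arrays.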
